A study of Mus musculus with 6 samples.

How the data were processed

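The series holds 6 RNA-seq libraries of mouse bone marrow mesenchymal stem cells, 3 titled siNC (control) and 3 titled siRIOK3 (RIOK3 knockdown), grouped and numbered by their titles. Per the labels' protocols, 2 μg of total RNA per library went into a stranded mRNA kit and PCR products of 200 to 500 bp were enriched. They were sequenced as paired-end reads of 150 bases on an Illumina NovaSeq instrument. HISAT2, MultiQC and the mouse build GRCm39 are named in the submitters' processing notes, with no version or role. The counting tool, its strand setting, the annotation release and any batch or date are not given in the sources used here. The authors deposited a table of raw counts per gene for 22030 genes, whose whole-number values sum to between 28327612 and 32569544 per library. The authors also deposited FPKM values of 21879 genes, which are counts scaled by gene length and library total and rounded. FPKM was used here only for alternatives. All columns of both tables were assigned to a library by name. Gene symbols, identifiers and chromosomes are those of the count table. Exon positions are not printed, because the reference used here, GENCODE M21 on GRCm38, is an earlier build than the one named by the submitters. That reference served only for the GC content and length of transcripts, matched by gene identifier without version, for 13043 (99.8%) of the tested genes. Each gene was represented by a single transcript, the one with the longest coding part, and among equals the longest. Genes without a coding transcript were represented by their longest transcript. The transcript used need not be the one expressed in these cells.

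Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 2 groups, which left 13067 genes holding 99.95% of the counts. Libraries were scaled by TMM (factors 0.915, 0.895 and 0.942 in control and 1.08, 1.09 and 1.10 in knockdown replicates 1, 2 and 3). The quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) compared the groups without covariates, two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested genes. A gene was called changed at an adjusted p under 0.05, with no fold threshold unless one is stated. Log2 fold changes are knockdown over control, levels are TMM-normalised CPM given as mean ± SD with n = 3 per group, and log2 CPM values used a prior count of 2. The biological coefficient of variation was 0.213, and the first 2 principal components of log2 CPM held 78.5% and 14.7% of the variance. The libraries detected 18047, 17530 and 17868 genes in control and 16968, 17151 and 16996 in the knockdown, and the 10 genes with most counts took between 8.34 and 9.07% of each library. The SDs given are spreads between libraries, which exceeded counting error in every pair of replicates. The SE of a log2 fold change is its size divided by the square root of the F statistic of the quasi-likelihood test. It thus rests on the variance estimates of that test, not on the SDs.

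The test, the filter, the groups, 36 gene lists and the rule for the genes to name were chosen before the data were examined. The lists cover osteogenic and other lineages, signalling, innate immunity, cell state, ribosomes, matrix, metabolism, markers of other cell types and RNA quality. The rule takes Riok3, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap in CPM and whose mean is at least 5 CPM in the higher group. Gene models and pseudogenes were left out. It adds up to 4 members with the smallest p of each list described, and Riok1, Riok2, Ifih1, Runx2, Sp7, Alpl, Bglap, Col1a1, Spp1, Ibsp, Pparg and Sox9. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. List counts are also given with p-values adjusted over the list alone. Aldoa and Atp5o each have 2 tested identifiers, so the glycolysis list has 33 tested entries from 32 genes in the table and the oxidative phosphorylation list 46 from 45. In the counts 66 genes share a symbol with another identifier.

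Other settings chosen beforehand were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile factors and library totals alone. Further ones were no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block and each library left out in turn. Limma-trend was run on log2(FPKM + 1) and on log2(FPKM + 0.1) of genes with an FPKM of at least 1 in 3 libraries, the former also without a filter. For lists, camera with an estimated correlation and fry were run. After the data were seen, corrections for sequence composition were added. In each, the trend of a library's log2 CPM, relative to the mean of the libraries, was fitted by loess (span 0.3, degree 1) and entered the edgeR fit as an offset. The trend was fitted on the GC content of the single transcript used for the gene, or on its GC content and log2 length. A composition offset was fitted on GC content, the adenine content of the coding sequence and log2 length. The GC offset and the GC and length offset were also run without control replicate 2. Such an offset removes any biological change that follows GC content together with a technical one, so uncorrected and corrected values are given side by side. After the GC offset the Spearman correlation of fold change with GC content across genes was 0.03.

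The tests were tried on simulated data drawn from the real means and library sizes, with 200 genes changed. Without a simulated GC trend, the edgeR test recovered 45.9% of 98 genes changed 2-fold and 93.8% of 97 changed 4-fold, and called 9 of 12699 unchanged genes. DESeq2 recovered 63% and 92% and called 33 of 12867, voom 41.8% and 93.8% with 10 of 12699, and limma-trend on log2(CPM + 1) 48.3% and 98.9% with 8 of 11370. With a straight GC trend of opposite sign in the groups simulated as well, the uncorrected test called 6299 of 12693 unchanged genes, the GC offset 10 of 12671 and the composition offset 9. The simulated trend used the same GC values that the offsets are fitted on. It was equal in all libraries of a group, with no trend on adenine content or length. These numbers thus do not give the error rate of the corrected calls in the real data. No list was shifted in these simulations, and camera called 0 lists without the trend, 2 with the trend uncorrected, 1 with the GC offset and 1 with the composition offset. In a separate simulation without a trend, 1 list was shifted 2-fold, and it was called and no other list was. Replicates were compared pair by pair with raw library totals: the chi-square statistic per gene lay between 7.22 and 279, so no pair agreed within sampling noise. Each library was counted as 1 sample, although this statistic cannot show that the libraries came from separate cultures.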

Results

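Messenger RNA of mouse bone marrow mesenchymal stem cells (mBMSCs), stromal progenitors that can form bone, fat and cartilage, was sequenced in 6 libraries that form 2 groups of 3. The control libraries are titled siNC and carry a wild-type genotype label, and the other libraries come from cells in which RIOK3 was knocked down. The design text describes stable lines made with lentivirus and also uses the word knockout, while the titles carry the prefix si. The labels do not settle which agent was used. Control replicates 1, 2 and 3 held 32569544, 31089006 and 31536610 counts over the 22030 genes of the count table, and knockdown replicates 1, 2 and 3 held 29722286, 30517261 and 28327612. The single comparison, RIOK3 knockdown against control, addresses how RIOK3 bears on the osteogenic differentiation of these cells. Culture medium and day of harvest are not given in the sources used here.

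Riok3, which encodes an atypical protein kinase of the RIO family, was lower in each of the 3 knockdown libraries than in any control library. The gene, ENSMUSG00000024404.8 on chromosome 18, had 4266, 5365 and 4022 counts in control replicates 1, 2 and 3, and 1034, 1048 and 1155 counts in knockdown replicates 1, 2 and 3. Its normalised level (CPM, with TMM scaling) was 157 ± 31.1 CPM in control and 33.6 ± 3.12 CPM in the knockdown (SD, n = 3 each), 4.68-fold lower. The log2 fold change was −2.23 (SE 0.178, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000127). Riok1 and Riok2, whose products are kinases of small ribosomal subunit maturation, fell too. Riok1 (ENSMUSG00000021428.10, chromosome 13) went from 128 ± 2.76 to 42.0 ± 1.19 CPM (log2 fold change −1.60, SE 0.113, adjusted p = 6.89e-05). Riok2 (ENSMUSG00000116564.2, chromosome 17) went from 54.5 ± 4.13 to 18.7 ± 0.285 CPM (log2 fold change −1.55, SE 0.125, adjusted p = 0.000122).

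Each library's trend on the GC content of transcripts was also removed, a correction chosen after the data were seen. The log2 fold change of Riok3 was then −1.31 (SE 0.225, adjusted p = 0.00616) and that of Riok1 −1.18, both past the threshold, and that of Riok2, −0.38, was not. Over its 22 alternatives Riok3 had log2 fold changes from −2.32 to −0.94 and adjusted p from 1.03e-25 to 0.0199. Riok1 lost its call, with a log2 fold change of −0.35, when adenine content and length were removed together with GC content.

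**Figure D1:**
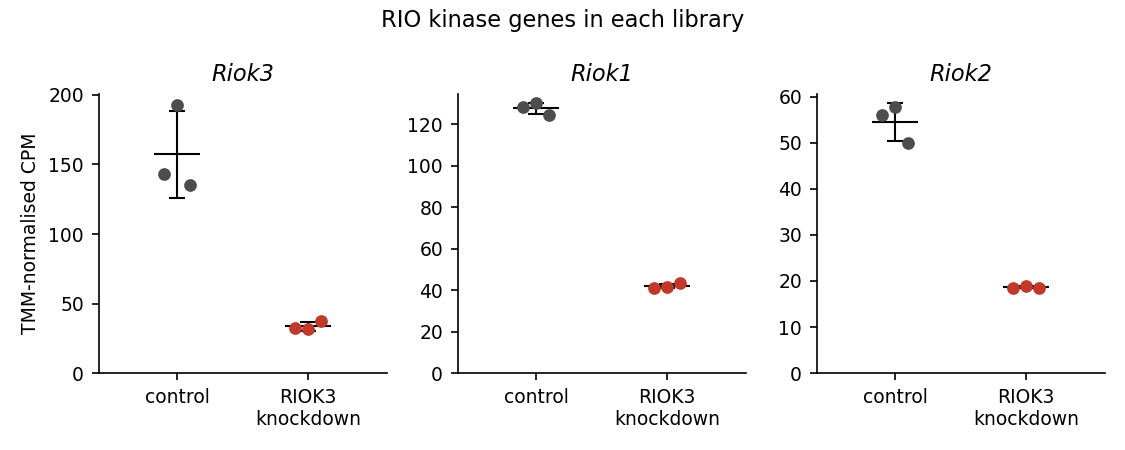
TMM-normalised CPM (linear axes from 0) of Riok3, Riok1 and Riok2 in the 3 control and 3 RIOK3 knockdown libraries, where each point is a library and the black marks are the mean and SD. The control means of 157, 128 and 54.5 CPM lie above the knockdown means of 33.6, 42.0 and 18.7 CPM, and the groups do not overlap for any of the 3 genes.

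Beyond Riok3, lists of genes of inflammation, cell cycle and ribosome assembly passed as lower in the knockdown libraries at a preset correlation of 0.01, and lists of glycolysis, matrix assembly and antigen presentation passed as higher. None of these 6 passed with an estimated correlation, without a correction or with the trend on GC content removed. The matrix list did not pass with that trend removed at the preset correlation either. Without a correction the estimate was −0.02 for the inflammation list and −0.01 for the glycolysis list, both below the preset value. Correlation between genes thus does not account for the lost calls of the inflammation and glycolysis lists there. The test with an estimated correlation therefore differs from the preset one in more than the correlation, and what else differs was not tested. Of 13067 genes tested, 6266 (48%) changed, 2758 of them higher and 3508 lower in the knockdown (edgeR, adjusted p under 0.05). An unadjusted p under 0.05 was found for 7254. A change of at least 2-fold was found for 3383 genes, 871 higher and 2512 lower, and one of at least 4-fold for 55 higher and 1129 lower. The control and knockdown libraries did not overlap in CPM for 8113 genes, 62.1% of those tested, where chance gives 10%. Fold changes followed the GC content of the transcripts, with a Spearman correlation of 0.70 and a Pearson correlation of 0.68 across 13043 genes, which are not independent replicates. Among the genes of 31.9 to 42.1% GC, the lowest decile, 1130 fell and 4 rose, with a median log2 fold change of −1.97. Among those of 58.3 to 75.9% GC, the highest decile, 661 rose and 17 fell, with a median of 0.64.

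The slopes of log2 CPM on GC content, relative to the mean of all 6 libraries, were −0.794, −0.450 and −0.640 per 10 points of GC in control replicates 1, 2 and 3. In knockdown replicates 1, 2 and 3 they were 0.662, 0.657 and 0.564. The centring on the mean of all libraries gives the groups opposite signs by construction, so a trend in a single group would look the same. With that trend removed, 3992 of 13043 genes changed, 1830 higher and 2162 lower, among which 2692 of the 6266 kept their direction and 231 were called in the opposite one. Control replicate 2 had Spearman correlations of log2 CPM of 0.963 and 0.968 with control replicates 1 and 3, against 0.996 between these. Without control replicate 2, 9592 genes changed, 4701 higher and 4891 lower, and 6223 of the 6266 kept their direction. The number of higher genes was 1653 without knockdown replicate 1 and 1647 without knockdown replicate 2. Of the changed genes 56% were lower under TMM scaling, 43.8% under upper-quartile scaling and 39.7% with library totals alone. The median log2 fold change of all tested genes was 0.01, 0.21 and 0.26, respectively. Nothing in the labels states that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

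**Figure D2:**
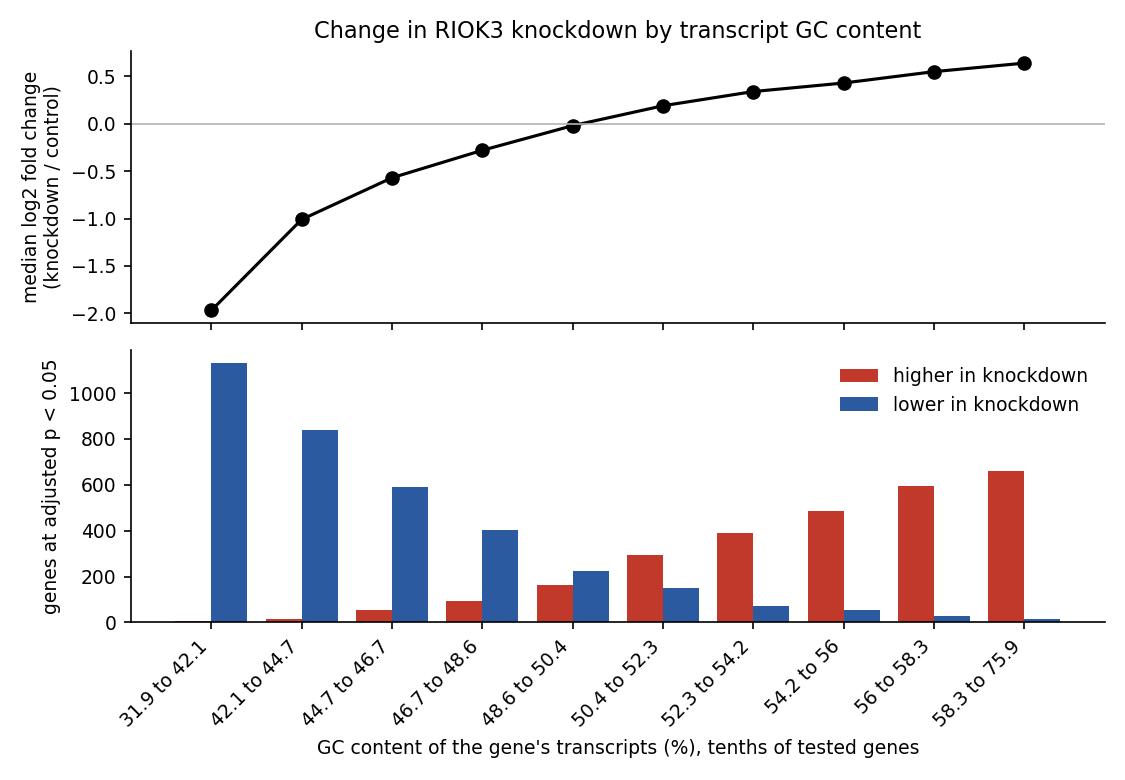
Median log2 fold change, knockdown over control (upper panel), and number of genes at an adjusted p under 0.05 (lower panel) in deciles of GC content. GC content is that of the single transcript used for each gene. The median goes from −1.97 at the lowest GC content to 0.64 at the highest, and genes that fell go from 1130 to 17 while genes that rose go from 4 to 661.

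**Figure D3:**
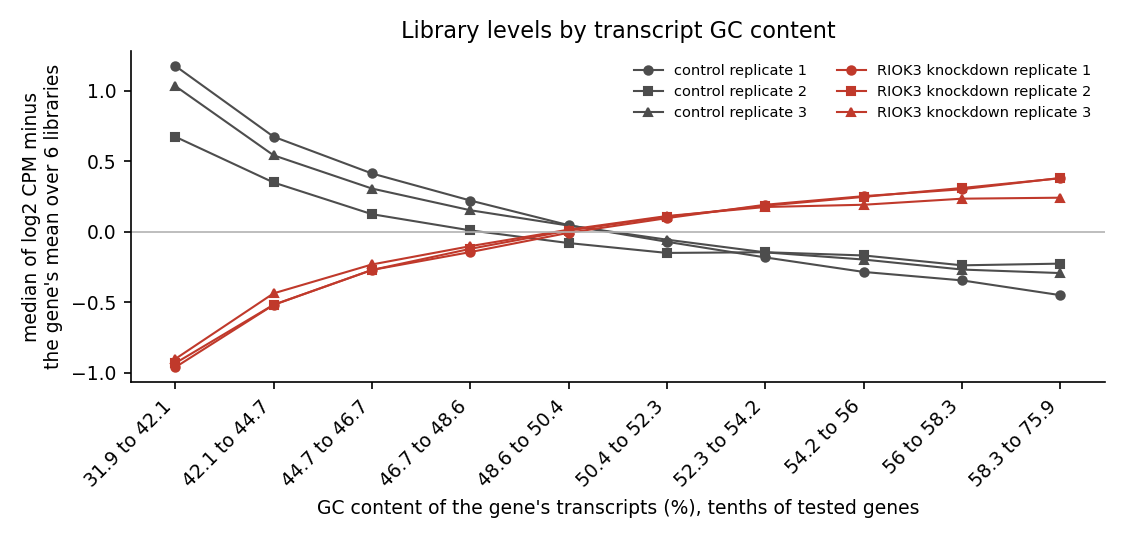
Median over genes of log2 CPM minus the gene's mean over the 6 libraries, in the same GC deciles, with a line for each library, control in grey and knockdown in red, and marker shapes for replicates 1, 2 and 3. In the decile of lowest GC the controls lie at 1.18, 0.68 and 1.04 and the knockdown libraries at −0.96, −0.93 and −0.90, and in the decile of highest GC the groups lie in the opposite order.

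Among the largest falls was Saa3, an acute-phase serum amyloid gene, which went from 32.8 ± 18.9 to 0.493 ± 0.256 CPM (log2 fold change −6.06, SE 0.560, adjusted p = 0.000236). Mki67, the proliferation marker Ki-67, went from 906 ± 268 to 16.8 ± 1.08 CPM (−5.75, SE 0.281, adjusted p = 2.82e-05). The mitotic kinesin genes Kif20b and Kif18a had log2 fold changes of −5.39 and −5.37, the neutrophil chemokine gene Cxcl5 −5.42, and Cep290, which encodes a protein of the ciliary transition zone, −5.32. Phip was at −5.55, Zfp677 at −5.39 and the inhibitory leukocyte receptor gene Lilrb4a at −5.37. The imprinted antisense RNA Kcnq1ot1, the mitochondrial ribosomal RNA mt-Rnr2 and the glutamate receptor gene Gria2 were at −5.28, −5.25 and −5.13. Saa3 has close paralogs, and Kcnq1ot1 overlaps another gene, so their counts are uncertain where the counting could share reads, since its strand setting is not given in the sources used here.

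Among the largest rises was Notch3, a Notch receptor, from 0.994 ± 0.574 to 5.36 ± 1.28 CPM (log2 fold change 2.42, SE 0.445, adjusted p = 0.00422). Itgb3, the integrin beta-3 subunit, went from 5.97 ± 1.04 to 25.2 ± 0.572 CPM (2.08, SE 0.165, adjusted p = 0.000121). Anxa6, a calcium-dependent membrane-binding protein, went from 38.1 ± 3.11 to 153 ± 2.21 CPM (2.01, SE 0.124, adjusted p = 4.17e-05). The semaphorin gene Sema4g was at 2.29, the imprinted RNA Peg13, which overlaps another gene, at 2.25, and the fibulin gene Fbln7 at 2.22. The unconventional myosin gene Myo7a was at 2.08, Hap1 at 2.04 and the corneodesmosin gene Cdsn at 1.99. Ppp1r13b, Ephb6 and Jrk were at 1.94, 1.92 and 1.88. These 12 rises and the 12 largest falls all passed in the same direction once the GC trend was removed. Saa3 was then at −6.27, Mki67 at −5.30, Gria2 at −2.58, Fbln7 at 2.13 and Ephb6 at 1.28. Gria2, at −2.41, was not past the threshold when length was removed too. With adenine content and length removed as well, Cep290 was at −0.99, Kcnq1ot1 at −1.71, mt-Rnr2 at −1.99, Kif20b at −2.09 and Mki67 at −3.38, all still past the threshold.

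NF-kB targets and inflammatory mediators fell as a group, with 21 of 31 tested members lower, none higher, a median log2 fold change of −1.67 and a camera adjusted p = 1.75e-06. Adjusted over the list alone, 21 fell and 1 rose. The list had a camera adjusted p = 0.095 with an estimated correlation, which was −0.02. Cxcl1, a neutrophil chemokine, went from 120.6 ± 7.05 to 5.28 ± 0.355 CPM (−4.51, SE 0.142, adjusted p = 1.86e-05). Ccl2, the monocyte chemoattractant, went from 97.2 ± 3.78 to 9.36 ± 1.22 CPM (−3.38, SE 0.150, adjusted p = 2.10e-05). Complement C3 fell by 1.89 on the log2 scale. After the GC trend was removed, 23 members fell, the median was −1.38 and the list stayed past the threshold (adjusted p = 0.066 with an estimated correlation). With adenine content and length removed as well, it also passed with an estimated correlation (adjusted p = 0.029), the only list to do so.

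Of 27 immediate early genes and feedback genes of MAPK signalling, 11 fell and 2 rose, with the same counts when adjusted over the list alone. The median was −0.28, and the list did not pass (camera adjusted p = 0.192). The AP-1 subunit genes Fos, Fosb and Jun were at −3.22, −3.20 and −1.19, and the ERK-induced gene Phlda1 at −1.21, all past the threshold. Once the GC trend was removed the list passed, with 12 lower, 2 higher and a median of −0.47 (adjusted p = 0.73 with an estimated correlation).

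Cell cycle genes were lower in the knockdown, with 24 of 48 lower and 4 higher (25 and 4 when adjusted over the list alone). Their median log2 fold change was −0.52 and the camera adjusted p = 0.00217 (adjusted p = 0.41 with an estimated correlation). Besides Mki67, Bub1, a kinase of the spindle checkpoint, went from 33.3 ± 7.26 to 2.66 ± 0.299 CPM (−3.65, SE 0.219, adjusted p = 4.17e-05). Kif23, a kinesin of cytokinesis, fell by 2.66 on the log2 scale, and Top2a, the topoisomerase of dividing cells, fell by 1.65. The list stayed past the threshold with the GC trend removed, with 20 lower, 2 higher and a median of −0.44 (adjusted p = 0.068 with an estimated correlation). Top2a was then at −0.59, and at 0.16 when adenine content and length were removed as well.

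Ribosome biogenesis genes, a list chosen because RIO kinases act in that process, fell in 26 of 45 cases and rose in 4 (27 and 4 when adjusted over the list alone). The median was −0.64 and the camera adjusted p = 0.000256 (adjusted p = 0.41 with an estimated correlation). Nop58, a protein of small nucleolar ribonucleoproteins, went from 467 ± 48.9 to 40.6 ± 2.45 CPM (−3.52, SE 0.144, adjusted p = 1.86e-05). Nucleolin, Ncl, went from 9607 ± 897 to 1761 ± 46.6 CPM (−2.45, SE 0.137, adjusted p = 3.10e-05). The nucleostemin gene Gnl3 fell by 2.36 on the log2 scale, and the dyskerin gene Dkc1 fell by 3.33. The GC-corrected median was also −0.64, with 24 lower and 1 higher and the list past the threshold (adjusted p = 0.66 with an estimated correlation). With adenine content and length removed as well, Ncl was at 0.27 and Nop58 at −0.51, and neither passed. These values rest on the single transcript used for each gene, of 8202 nt for Ncl and 9507 nt for Nop58. Other transcripts were not tried, so the lost calls may depend on that choice. Of the ribosomal protein genes, 3 of 33 of the small subunit and 7 of 48 of the large subunit fell and none rose. These counts were 0 and 1 when adjusted over the list alone. Neither list passed (camera adjusted p = 0.447 and 0.374), although the large subunit did so without control replicate 1 (adjusted p = 0.0446) or control replicate 3 (adjusted p = 0.048), and with the GC trend removed (adjusted p = 0.032). With an estimated correlation, which was 0.93 for this list, its adjusted p was 1, and 0.97 with the GC trend removed. At the preset correlation the large subunit did not pass with GC content and length removed (camera adjusted p = 0.2). Nor did it with the composition offset (0.5), or with the GC offset and control replicate 2 left out (0.99). Without control replicate 2 and uncorrected, the balance turned, with 15 higher and 9 lower of the small subunit (median 0.10) and 26 higher and 17 lower of the large subunit (median 0.23).

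Interferon-stimulated genes went both ways, with 17 of 51 higher and 18 lower (17 and 19 when adjusted over the list alone). Their median log2 fold change was −0.04 and the camera adjusted p = 0.954. The antiviral gene Ifit1 went from 135 ± 16.1 to 11.6 ± 1.49 CPM (−3.54, SE 0.168, adjusted p = 2.68e-05) and the DNA sensor gene family member Ifi204 from 117 ± 14.8 to 16.1 ± 1.0 CPM (−2.87, SE 0.151). The immunity-related GTPase gene Iigp1 fell by 3.03 on the log2 scale. Ifit1 and Ifi204 have close paralogs, so their levels are uncertain. The median of this list was 0.01 without control replicate 2 and 0.13 without knockdown replicate 2. It was 0.22 with the GC trend removed, 0.15 under upper-quartile scaling and 0.21 with library totals alone.

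In the RNA sensing pathway, 6 of 18 genes rose and 7 fell, with the same counts when adjusted over the list alone. The median was 0.18, the mean −0.36 and the test pointed down without passing (camera adjusted p = 0.999). Ifih1, the cytosolic RNA sensor MDA5, which RIOK3 is known to phosphorylate, went from 38.2 ± 3.55 to 5.25 ± 0.664 CPM (−2.87, SE 0.159, adjusted p = 3.10e-05). The endosomal sensor gene Tlr3, the kinase gene Tbk1 and the TBK1 adaptor gene Azi2 were at −2.13, −1.26 and −1.33, all past the threshold. After the GC correction Ifih1 (−1.67) and Tbk1 (−0.61) stayed past it, and Tlr3 (−0.28) and Azi2 (−0.17) did not. Azi2, at 0.27, was called in the opposite direction with adenine content and length removed as well. The GC-corrected list had 4 higher, 3 lower and a median of −0.06.

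Osteoblast differentiation genes, which the study's question concerns, did not move one way. Of 15 tested genes 6 rose and 4 fell, with the same counts when adjusted over the list alone. The median log2 fold change was 0.65, the mean −0.04, and the test pointed up without passing (camera adjusted p = 0.447). Col1a1, the main chain of bone collagen, went from 17.6 ± 0.634 to 46.0 ± 1.15 CPM (1.39, SE 0.118, adjusted p = 0.00015). Alpl, the tissue-nonspecific alkaline phosphatase, went from 1.92 ± 0.564 to 4.75 ± 0.611 CPM (1.31, SE 0.260, adjusted p = 0.00581). Spp1, osteopontin, went from 572 ± 73.2 to 148 ± 4.97 CPM (−1.95, SE 0.138, adjusted p = 7.34e-05). Phex and Enpp1, genes of phosphate and pyrophosphate metabolism in bone, were at −4.01 and −1.47, both past the threshold. Sp7, Bglap and Ibsp, markers of committed and mature osteoblasts, were below the count filter, with at most 2 counts in any library.

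Runx2, the master transcription factor of the osteoblast lineage, was at 25.7 ± 5.02 CPM in control and 25.4 ± 1.08 CPM in the knockdown (log2 fold change −0.02, SE 0.172, adjusted p = 0.946). It was at 0.19 under upper-quartile scaling, at 0.23 with library totals alone and between −0.17 and 0.07 when 1 library was left out. With the GC trend removed Runx2 was at −0.56 without passing (adjusted p = 0.0514). It was called lower when control replicate 2 was left out as well, at −0.73, and at −0.75 with length also removed (adjusted p = 1.34e-07). These corrected values rest on the single transcript used for Runx2, of 1791 nt and 56.8% GC. Other transcripts of the gene were not tried, so the corrected call may depend on that choice. With the GC trend removed and all 6 libraries, Col1a1 (0.77), Alpl (0.79) and Spp1 (−1.11) kept their direction and stayed past the threshold, although Col1a1, at 0.54, was not past it once length was removed too. The corrected osteoblast list had 2 higher, 4 lower, a median of 0.15 and a test that pointed down without passing.

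Of 18 adipocyte genes 8 rose and 3 fell (10 and 3 when adjusted over the list alone). The median log2 fold change was 0.52, and the list did not pass (camera adjusted p = 0.105). Cebpa, an adipogenic transcription factor, went from 7.42 ± 1.51 to 21.4 ± 3.03 CPM (1.52, SE 0.196, adjusted p = 0.000916), and Zfp423, a factor of preadipocyte commitment, was at 1.26 and past the threshold. Lpl, lipoprotein lipase, went from 93.4 ± 7.07 to 34.8 ± 0.952 CPM (−1.42, SE 0.122, adjusted p = 0.000152), and the fatty acid carrier gene Fabp4 fell by 2.12 on the log2 scale. Pparg, the main regulator of adipogenesis, was at 15.9 ± 2.36 and 16.5 ± 0.234 CPM (0.05, SE 0.148, adjusted p = 0.796). The GC-corrected list had 6 higher, 3 lower and a median of 0.27. Pparg was then past the threshold at 0.68 and Fabp4, at −0.38, was not. In the cartilage list 1 of 7 genes rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.947). Sox9, the chondrocyte transcription factor, went from 23.8 ± 4.94 to 15.5 ± 0.674 CPM (−0.62, SE 0.179, adjusted p = 0.0263). This call was lost when any library other than control replicate 2 was left out (log2 fold changes from −0.64 to −0.49), with library totals alone and on the FPKM scales.

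Among 21 marrow stromal markers 5 rose and 9 fell (6 and 9 when adjusted over the list alone). The median was −0.26 and the list did not pass (camera adjusted p = 0.455). The adhesion receptor genes Alcam and Vcam1 were at −2.57 and −1.45, Kitl, stem cell factor, at −4.82, and Gas6, a ligand of TAM receptors, at 1.3. These 4 passed the threshold, as they did in the same direction with the GC trend removed, when the list had 3 higher, 7 lower and a median of −0.25.

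Genes of collagens and matrix assembly were higher as a group, with 22 of 41 higher and 6 lower (23 and 7 when adjusted over the list alone). Their median log2 fold change was 0.69 and the camera adjusted p = 0.00564 (adjusted p = 0.76 with an estimated correlation). Adamts2, the procollagen N-proteinase, went from 35.4 ± 4.68 to 117 ± 3.27 CPM (1.72, SE 0.139, adjusted p = 0.000123). P4ha2, a prolyl 4-hydroxylase subunit, went from 33.7 ± 2.35 to 91.0 ± 1.82 CPM (1.43, SE 0.120, adjusted p = 0.000139). Versican, Vcan, fell by 3.20 on the log2 scale. With control replicate 2 left out, 28 were higher and 11 lower, and the list stayed called. Removing the GC trend left 11 higher, 8 lower and a median of 0.36, and ended the call of the list. Adamts2 (1.33), P4ha2 (1.06) and Vcan (−2.22) each still passed.

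In the BMP pathway 5 of 20 genes rose and 6 fell, with the same counts when adjusted over the list alone. The median was 0.20, the mean −0.13, and the test pointed up without passing (camera adjusted p = 0.954). The BMP antagonist gene Grem1 went from 83.6 ± 25.2 to 6.62 ± 1.04 CPM (−3.66, SE 0.274, adjusted p = 0.000101). The ligand gene Bmp4 went from 4.52 ± 0.880 to 0.872 ± 0.122 CPM (−2.37, SE 0.235, adjusted p = 0.000295). The inhibitory SMAD gene Smad6 was at 1.80 and the receptor gene Bmpr1a at −1.44, both past the threshold. The GC-corrected values of Grem1, Bmp4 and Smad6 were −2.87, −2.65 and 1.13, all past the threshold, and that of Bmpr1a, 0.12, was not. The corrected list had 4 higher, 3 lower and a median of 0.17. Without control replicate 2 and uncorrected, 9 of its genes rose and 7 fell, which turned the balance.

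Antigen presentation by MHC class I was higher, with 14 of 22 genes higher and 2 lower (16 and 3 when adjusted over the list alone). The median log2 fold change was 0.73 and the camera adjusted p = 0.00564 (adjusted p = 0.6 with an estimated correlation). Tap1, a subunit of the peptide transporter, went from 23.3 ± 2.45 to 64.4 ± 6.45 CPM (1.47, SE 0.147, adjusted p = 0.000299). H2-T23, a class Ib molecule that shares sequence with its paralogs, was at 0.97, and the chaperone gene Canx and the peptide trimming gene Erap1 were at −1.11 and −0.96, all past the threshold. The list stayed past it with the GC trend removed, with 6 higher, none lower and a median of 0.36 (adjusted p = 0.73 with an estimated correlation). Canx was then at 0.24 without passing, and Erap1, at 0.54, was called in the opposite direction.

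Glycolysis and hypoxia response genes rose in 17 of 33 cases and fell in 1, also when adjusted over the list alone. The median was 0.71 and the camera adjusted p = 3.72e-05 (adjusted p = 0.095 with an estimated correlation, which was −0.01). Ndrg1, a hypoxia-induced gene, went from 179 ± 12.5 to 382 ± 9.09 CPM (1.09, SE 0.117, adjusted p = 0.000396). Egln1, the oxygen-sensing prolyl hydroxylase, went from 41.4 ± 2.67 to 87.8 ± 1.57 CPM (1.09, SE 0.117, adjusted p = 0.000415), and Pgam1, phosphoglycerate mutase, was at 0.97 and past the threshold. Bnip3l, a mitophagy receptor, was the member that fell, with a log2 fold change of −1.14, and was at 0.24 without passing once the GC trend was removed. Of the corrected list 13 rose, none fell, the median was 0.49 and the call held (adjusted p = 0.068 with an estimated correlation).

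Transcripts of the mitochondrial genome fell in 13 of 14 cases and none rose, also when adjusted over the list alone. Their median log2 fold change was −1.79 and the camera adjusted p = 1.06e-05 (adjusted p = 0.41 with an estimated correlation). They took 1.82, 1.26 and 1.70% of the counts in control replicates 1, 2 and 3 and 0.714, 0.734 and 0.773% in knockdown replicates 1, 2 and 3. The ATP synthase gene mt-Atp6 and the cytochrome oxidase gene mt-Co3 were at −4.28 and −2.95, both past the threshold. The complex I gene mt-Nd4 went from 655.5 ± 74.8 to 204 ± 8.29 CPM (−1.68, SE 0.135, adjusted p = 0.000121). These transcripts are poor in GC, with a list median of 36.5%. After removal of the GC trend 7 rose and 2 fell, the median was 0.84 and the list was not called, with mt-Nd4 at 1.25 and called in the opposite direction. Of 46 nuclear genes of oxidative phosphorylation 6 rose and 9 fell (5 and 9 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.971). Without control replicate 2, 21 of them rose and 11 fell, and the median went from −0.09 to 0.14.

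Among 9 histone and nuclear-retained RNAs 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.801). The median of −0.36 was 0.21 with the GC trend removed. Without control replicate 2 it was 0.09 over the same 9 genes, and 0.40 over the genes that passed the filter there. The long nuclear RNA Malat1 went from 1593 ± 368 to 72.6 ± 9.04 CPM (−4.46, SE 0.222, adjusted p = 2.82e-05). The paraspeckle RNA Neat1 was at −1.55 and the linker histone gene H1f0 at 1.31, both past the threshold. With the correction Malat1, Neat1 and H1f0 were at −3.18, −1.22 and 1.07, all past the threshold.

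In the other signalling lists, Hedgehog genes rose in 10 of 13 cases and fell in 2, without a list call (camera adjusted p = 0.0506). They passed without control replicate 1, control replicate 3, knockdown replicate 1 or knockdown replicate 2 (adjusted p from 0.0203 to 0.0492). With all libraries and an estimated correlation, which was 0.39 for this list, the adjusted p was 0.76. With the GC trend removed 3 Hedgehog genes rose, 1 fell, the median went from 0.92 to 0.38 and the list was not called (camera adjusted p = 0.14). TGF-beta response genes rose in 10 and fell in 7 of 25 cases (camera adjusted p = 0.548). Wnt pathway genes rose in 7 and fell in 2 of 26 (0.157 for the list), and Notch pathway genes rose in 4 and fell in 2 of 14 (0.473). Genes of the unfolded protein and integrated stress response rose in 16 and fell in 5 of 32 cases (camera adjusted p = 0.0667, and 0.026 without control replicate 2, against 0.74 with an estimated correlation and all libraries). With the GC trend removed 5 TGF-beta genes rose and 6 fell, 6 Wnt genes rose and 1 fell, 2 Notch genes rose and 4 fell, and 7 stress response genes rose and 2 fell, with no list called. Targets of p53 rose in 7 and fell in 8 of 28 cases, and matrix proteases and inhibitors rose in 7 and fell in 6 of 25. Contractile smooth muscle genes rose in 4 and fell in 2 of 15, and autophagy and lysosome genes rose in 10 and fell in 5 of 39. Genes by which stromal cells regulate osteoclasts rose in 2 and fell in 2 of 7. With control replicate 2 left out, 11 Wnt genes rose and 5 fell, 4 Notch genes rose and 5 fell (median 0.21, from 0.51), and 23 autophagy and lysosome genes rose and 11 fell. The lists of p53 targets, proteases, smooth muscle, autophagy and osteoclast regulation were not called with all libraries (camera adjusted p from 0.208 to 0.999). When adjusted over the list alone, the counts with all libraries were the same except for TGF-beta (10 and 8), the stress response (17 and 5) and autophagy (7 and 5). The medians of p53 targets, matrix proteases and osteoclast regulation were 0.13, 0.09 and 0.04 and their means −0.25, −0.27 and −0.35, with tests that pointed up, up and down.

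Markers of other cells were sparse. Of 20 macrophage and monocyte markers with counts 4 were tested and 1 rose, and of 8 granulocyte, mast and lymphoid markers 1 was tested and fell. Of 8 erythroid and megakaryocyte markers 4 were tested, with 1 higher and 1 lower. Of 13 endothelial markers 6 were tested, with 1 higher and 1 lower (camera adjusted p = 0.954). Of 15 epithelial and neural markers 3 were tested, with 2 higher and 1 lower. Adjusted over the list alone, these counts differed only for the erythroid markers, with 2 higher and 1 lower.

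Of the 36 gene lists 32 had at least 5 tested members, and camera with a preset correlation of 0.01 called 7 of them (11 at an unadjusted p under 0.05). With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05). The rotation test fry, which asks whether the genes of a list move on balance in 1 direction and does not set them against other genes, called 19. The other 9 ways of dividing the 6 libraries into 3 and 3 gave between 5 and 12 called lists. Each of them has libraries of both groups on each side, so part of the group difference stays between its sides.

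**Figure D4:**
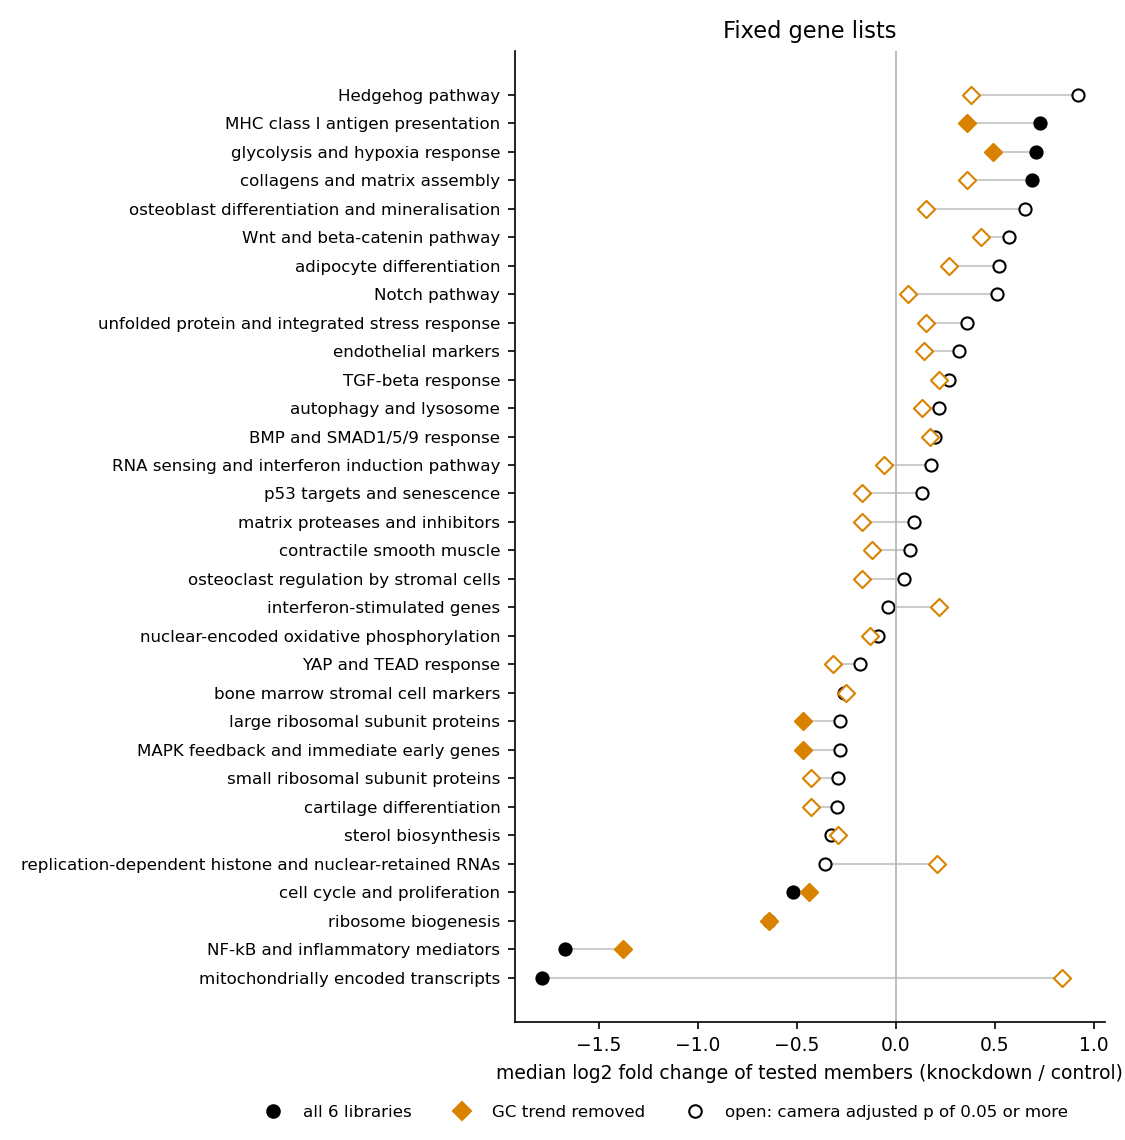
Median log2 fold change, knockdown over control, of the tested members of the 32 gene lists, from all 6 libraries (black circles) and with the GC trend removed (orange diamonds), filled where the camera adjusted p with the preset correlation was under 0.05. NF-kB and inflammatory mediators lie at −1.67 and −1.38 and glycolysis and hypoxia response at 0.71 and 0.49, while mitochondrially encoded transcripts go from −1.79 to 0.84.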

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

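The 5 corrections for sequence composition were chosen only after the data were seen, and all other settings were chosen beforehand. Depth was similar in the 6 libraries, at 28327612 to 32569544 counts. Sp7, Bglap and Ibsp had at most 2 counts in any library and were not tested, and whether depth or absent expression accounts for this was not tested. Riok3 was lower and past the threshold in all 22 alternatives, with log2 fold changes from −2.32 to −0.94. Of the other 92 named genes, 90 kept their direction in every setting chosen beforehand that gave a value, with Runx2 and Pparg as the exceptions. Of the 90 called with all libraries 89 stayed called there, with Sox9 as the exception (−0.37 with library totals alone, −0.26 on log2(FPKM + 1), and in 5 of the 6 fits with a library left out). Over these settings 1504 of the named-gene values kept direction and side of the threshold, 9 lost the call and 9 reversed. Over the corrections 401 kept both, 24 lost the call, 7 gained one and 28 reversed. For the medians of the 17 lists described, 185 kept both, 7 lost the call, 6 gained one and 6 reversed in the settings chosen beforehand, and 50, 5, 10 and 20 did in the corrections. For the changes listed below the cause was not tested.

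The counts of genes and lists and the Riok3 fold change were compared with those from all libraries. Of these values 83 from settings chosen beforehand were kept and 14 were not, and for the corrections 22 were and 8 were not. A count was kept within 1.5 times, and the Riok3 fold change if it kept direction and side of the threshold, whatever its size. Riok3 was always kept, although it was between −1.31 and −0.94 in the corrections, against −2.23. When 1 library was left out, the number of changed genes ranged from 4340 to 9592 (6266 with all libraries), with the highest without control replicate 2. The number of higher genes ranged from 1647 to 4701 (2758), with the lowest without knockdown replicate 2, 1653 without knockdown replicate 1 and the highest without control replicate 2. Voom with sample quality weights gave 9477 changed and 4673 higher genes. Library totals alone gave 4280 higher genes. The log2(FPKM + 1) scale gave 1993 lower genes and 1724 changed at least 2-fold, log2(FPKM + 0.1) gave 1992 lower genes, and log2(FPKM + 1) without a filter gave 4175 higher genes and 1707 at least 2-fold. The GC offset gave 3992 changed genes, 1830 higher and 2162 lower, with 1909 at least 2-fold (3383 with all libraries and no offset). The GC and length offset gave 1920 at least 2-fold and, without control replicate 2, 4317 higher genes. The composition offset gave 2201 lower genes (3508) and 1660 at least 2-fold. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05) and fry called 19, against 7. With the composition offset and an estimated correlation 1 list, NF-kB targets, was called.

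Runx2 turned from −0.02 to 0.19 under upper-quartile factors, 0.23 with library totals alone, 0.20 on log2(FPKM + 1) with and without the filter and 0.27 on log2(FPKM + 0.1). It ranged from −0.17 to 0.07 when 1 library was left out. Pparg ranged from −0.05 to 0.17 when 1 library was left out, with the lowest without control replicate 1. The list medians ranged from −0.07 to 0.13 for interferon-stimulated genes, from −0.57 to 0.40 for histone and nuclear-retained RNAs (over the genes that passed the filter in each fit) and from −0.26 to 0.01 for YAP and TEAD targets when 1 library was left out. The histone value without control replicate 2 was 0.09 over the 9 genes tested with all libraries. Library totals alone gave 0.21 for the interferon list and 0.07 for the YAP list.

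The corrections turned the following values, given in the order GC, GC and length, composition, GC and length without control replicate 2, GC without control replicate 2. Log2 fold changes were 0.12, 0.27, 0.02, 0.35 and 0.10 for Bmpr1a, 0.24, 0.30, 0.47, 0.35 and 0.24 for Canx, 0.54, 0.66, 0.62, 0.86 and 0.63 for Erap1, and 1.25, 0.86, 0.97, 0.83 and 1.35 for mt-Nd4. Bnip3l was at 0.24, 0.20, 0.26 and 0.30 in those other than composition. Composition alone turned Azi2 (0.27), Top2a (0.16) and Ncl (0.27), and the GC offset without control replicate 2 turned Fabp4 (0.20). Runx2 was called only without control replicate 2, under the GC offset (−0.73) and the GC and length offset (−0.75). Pparg was called in all 5 corrections (from 0.57 to 0.89). List medians were 0.22, 0.38, 0.30, 0.41 and 0.31 for interferon-stimulated genes, −0.06, −0.11, −0.04, −0.12 and −0.12 for RNA sensing, 0.84, 0.51, 0.12, 0.43 and 0.84 for mitochondrially encoded transcripts, and 0.21, 0.55, 0.41, 0.65 and 0.61 for histone and nuclear-retained RNAs. The lists of NF-kB targets, MHC class I, cell cycle, ribosome biogenesis and glycolysis were called in 16 of 17 settings, that of collagens in 11 and that of mitochondrial transcripts in 11.

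The replicate numbers are shared by the groups, but deviations from the group mean correlated at −0.08, 0.04 and 0.05 for numbers 1, 2 and 3. The own number was the best match for 1 of the 3, which gives no sign of pairing. With 3 libraries per group this cannot exclude a shared culture or day, which the labels do not state. With the replicate block 5615 genes changed, 2390 higher and 3225 lower, 3337 at least 2-fold, Riok3 was at −2.21 and 8 lists were called.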

Other observations

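The tests of gene families with a common name, of mitochondrial transcripts, of a batch and of Riok3, and the corrections for sequence composition, were chosen only after the results were seen. All 6 tested SMC genes, whose proteins form cohesin, condensin and related complexes, fell, with a median log2 fold change of −4.03, and all 6 fell with the GC trend removed, at a median of −2.37. Of 326 zinc finger genes (symbols starting with Zfp), 175 fell and 47 rose, with a median of −0.85, and 103 fell and 34 rose at a median of −0.28 with that trend removed. Of 39 centrosomal protein genes (Cep) 20 fell and 4 rose at a median of −0.65, and of 30 kinesin genes (Kif) 13 fell and 4 rose at a median of −0.47, with 17 and 13 lower after the correction. Histocompatibility genes (H2-), many of them close paralogs, rose in 11 of 19 cases and fell in 2 at a median of 0.69 (camera adjusted p = 0.0025). With the trend removed 4 rose and 2 fell at a median of 0.34, and the group was not called (0.22). Integrin subunit genes rose in 6 of 16 and fell in 6. Solute carrier genes (Slc) rose in 55 of 189 cases and fell in 31, at a median of 0.24 with all libraries and 0.25 with the trend removed. The directions of the SMC, Zfp, Cep, Kif, H2- and Slc medians were the same under TMM, RLE, upper-quartile and library-total scaling. None of these families was summarised with adenine content and length removed as well, so whether their changes hold under that correction was not tested.

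Of 21 targets of YAP and TEAD, the effectors of Hippo signalling, 6 fell and 4 rose, the same counts as when adjusted over the list alone. The median of −0.18 (camera adjusted p = 0.954) was 0.02 under upper-quartile scaling, 0.07 with library totals alone and 0.01 without control replicate 1. Ankrd1 fell from 1213 ± 252 to 361 ± 10.7 CPM (SD, n = 3; −1.75, SE 0.176, edgeR adjusted p = 0.00033). The tissue factor gene F3 fell from 125 ± 1.94 to 47.5 ± 1.67 CPM (−1.40, SE 0.112) and Gadd45a fell by 1.14 on the log2 scale, while Ccn1 rose by 0.67. All 4 passed in the same direction with the GC trend removed, when the list had 7 lower and 1 higher. The list was called with the GC and length offset (adjusted p = 0.045), the composition offset (0.043) and the GC offset without control replicate 2 (0.0022), in 4 of 17 settings. With an estimated correlation it was not (0.75 with the GC offset and 0.63 with the composition offset). Of 23 sterol biosynthesis genes 10 fell and 2 rose, also when adjusted over the list alone, without a list call (median −0.33, camera adjusted p = 0.129), and 6 fell and 1 rose with the GC trend removed. Under the composition offset 8 fell and none rose and the list was called (adjusted p = 0.003, and 0.21 with an estimated correlation), as in 2 of 17 settings. Idi1, isopentenyl diphosphate isomerase, fell from 7.87 ± 2.29 to 0.753 ± 0.133 CPM (−3.38, SE 0.298). The sterol carrier gene Stard4, Msmo1 and the sterol sensor gene Insig1 were at −1.56, −1.03 and −0.82, all past the threshold. Of these 4 Msmo1, at −0.38, was not past it after the GC correction. Rnf217 was called only after the correction (0.31 before and 2.55 after). The mitophagy receptor gene Bnip3 was called before it too and was higher after it (0.90 and 2.38), and Memo1 turned from −0.50 to 2.14. These genes were picked after their values were seen.

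Fold changes followed the GC content of transcripts. The slope on GC in 495 lncRNA genes was 0.94 per 10 points against 1.32 in protein-coding genes. The ratio was 0.72 (95% bootstrap interval 0.55 to 0.89, where under 0.5 was required for an effect through the coding sequence of translated mRNAs). These values argue against the coding sequence as the only source. The interval lies wholly below equal slopes, so a contribution of the coding sequence stays open. All 15 tested genes of the mitochondrial chromosome are the 14 of the list and the transfer RNA mt-Tl1. Their median differed by −1.7 from that of all genes, and 13 of 15 were lower. This test was set after their fall was seen, and it cannot tell the same trend from a separate mitochondrial change. An effect confined to transcripts of the nuclear genome thus stays open. The slopes argue against variation of the size seen between libraries of the same group, since the gap between the group slopes was 3.65 times the widest range within a group. That range may be technical, so it does not measure the variation between separate cultures or preparations. A library preparation or RNA batch that coincides with the groups cannot be told apart from an effect of the knockdown, because no batch is labelled and the exact two-sided permutation test of 3 against 3 slopes cannot give a p under 0.1, the value found (p = 0.1). Both may contribute.

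The fall of Riok3 was not accounted for by the GC trend alone, since it was at −1.31 (SE 0.225) with that trend removed and stayed past the threshold. It was also not unusual among genes of like GC content and expression: it lay at percentile 14.2, with 36 of 254 matched genes at or below it, a matched median of −1 and a 5th percentile of −3.39. This is consistent with the general scatter of such genes. With the GC trend removed it exceeded the fall of Riok2 by 0.93 (a difference of −3.43 standard errors, and −2.25 with the composition trend removed), but that of Riok1 by only 0.14 (−0.53 standard errors, and −2.30 with the composition trend removed). A fall of the same size in Riok1 thus cannot be told apart from that of Riok3, because the 2 corrections give different answers. The knockdown stays open as the explanation of the Riok3 values, and these libraries alone may not separate it from the wider change.

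Control replicate 2 stood apart from the other 2 control libraries, with chi-square statistics per gene of 279 and 235 against them and 15.6 between them. Its deviation from them fell with transcript length within each of 5 bins of GC content, with rank correlations across genes, which are not independent, from −0.62 to −0.42. The median deviation was 0.54 for transcripts of 74 to 1513 nt and −0.70 for those of 4782 nt or more. Lower recovery of long transcripts, for example through RNA fragmentation before selection, is a candidate explanation. The slope of this library on GC content was 0.27 from that of the other controls and 1.08 from that of the knockdown libraries, a ratio of 0.25. It thus does not share the full GC trend that separates the groups. A part of that trend stays open, since its slope of −0.450 lay toward the knockdown, against −0.794 and −0.640 in control replicates 1 and 3. The library's deviation had Spearman correlations across genes of 0.23 with GC content and −0.57 with length. No biological explanation was tested for this library.

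Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 6266 changed genes, and the highest of the others gave 0 (edgeR). For gene lists, 8 of the 10 splits gave at least the 7 lists of the real one, and the highest of the others gave 12. Every other split has libraries of both groups on each side. Part of the group difference thus stays between its sides, and the rest adds to the spread within them. These splits therefore do not show what unrelated groups would give, for genes or for lists. With 10 splits the share cannot go under 0.1.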
